A study of Mus musculus with 26 samples.

How the data were processed

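RNA from mouse S49 T lymphoma cells, wild type (WT) and the deathless variant (D-), was hybridised to 26 single-colour Affymetrix arrays, 1 array per sample. Per the labels, cells were untreated or treated with 8-CPT-cAMP for 2, 6 or 24 h. Group and replicate number were taken from the labels. Titles of treated WT samples say untreated with a time, but their source and description fields say treated, and they were used as treated. The labelled dose, 100 mM, looks too high for cell culture, may be a unit error and only told treated from untreated samples.

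Per the labels, the authors summarised each probe set with GCRMA, and the deposited intensity values lie on a linear scale, between 2 and 83530.7. The version of GCRMA, and whether both lines were normalized in 1 run, are not given in the sources used here. GCRMA corrects background from probe sequence and equalises the distribution of intensity between arrays, so a change shared by most probe sets would not be seen, and it compresses values near its floor. Log2 of the deposited intensity was taken here, with no pseudocount and no further normalization. The table held 22690 probe sets, of which 64 were array controls and were left out. By the platform annotation, 20380 probe sets had 1 gene symbol, 691 several and 1555 none, and no gene was named from a probe set with several symbols. All per-sample value columns were used.

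Probe sets at or above log2 5 (intensity 32) on at least 3 arrays were tested, 12724 in all, and the probe set with the highest mean stood for each of 7435 genes. The deposited intensity has no detection call, so a change to or from a group mean under log2 5 is given as a bound, the difference between the brighter mean and 5, and where both means lay under 5 no fold is given. A difference of response with such a group mean is a fitted value. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to all 26 arrays with 8 group means, with 18 residual and 3.34 prior degrees of freedom. Its 10 contrasts were each treated time against untreated in each line, untreated D- against untreated WT, and the D- minus WT difference of response at each time, as an interaction. p-values were adjusted by Benjamini-Hochberg within each contrast over all probe sets tested, and calls were made at adjusted p under 0.05. At an unadjusted p under 0.05, chance alone would call 636 probe sets in a contrast.

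Before the data were examined, 23 gene lists with 518 genes were fixed, from textbook knowledge: CREB targets, cAMP and PKA pathway, G1, S phase, mitosis, pro- and anti-apoptotic, p53 targets, glucocorticoid-responsive, T cell, B cell, myeloid, erythroid, stromal, interferon, cytokine receptor and JAK-STAT, glycolysis, oxidative phosphorylation, cholesterol, ribosome biogenesis and MYC targets, unfolded protein and amino acid stress, heat shock, and chemokine receptor and adhesion genes. Some genes stand in more than 1 list, which gives 533 entries. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The calls that held with the estimated correlation were those of CREB targets at 2 h in both lines and at 6 h in D-, of glucocorticoid-responsive genes at 2 h in D- and of heat shock genes for the difference of response at 6 h. The mean of a list per array was compared between the lines with an exact permutation test.

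The rule for naming genes, also fixed before the data were examined, took per comparison the 12 highest and 12 lowest log2 changes among called genes whose arrays all lay on 1 side of the reference mean, the 4 members of each list with the largest change, and 17 genes named in any case. Of this pool the text prints called genes, chosen for readability after the values were seen, plus the fixed genes whether called or not. Of these Pde4d had no probe set with that symbol alone and was not analysed here. The 2 clusters of arrays are the 2 signs of the first axis of deviations from group means and are not in the labels. Fits by cluster were therefore chosen after seeing the data.

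The limma fit was tested on simulated data with the real probe set means and spreads, and its rates may not hold with array clusters. For WT at 24 h, with 12724 probe sets, it recovered 28.4%, 79.1% and 100% of simulated log2 changes of 0.5, 1 and 2, with 4 false calls, and for the difference of response at 24 h it recovered 11.9%, 58.2% and 97%, with 3 false calls. Alternatives were eBayes with trend and robust settings, array weights, only the groups compared, quantile normalization added, median centring, filters at log2 7 or none, the mean of all probe sets of a gene, the replicate number as a block, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.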

Results

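S49 is a mouse T lymphoma cell line whose wild-type (WT) cells stop dividing and then die when cyclic AMP (cAMP) is raised. D- is a variant of S49, named deathless because its cells survive raised cAMP. Cells of both lines were treated with 8-CPT-cAMP, a membrane-permeable cAMP analogue that activates protein kinase A (PKA), at a dose that the labels give as 100 mM. That unit may be an error. RNA was measured on single-colour Affymetrix arrays before treatment and after 2, 6 and 24 h, which asks which genes respond to cAMP in cells that die of it and in cells that do not. The 26 arrays fall into 8 groups, with 4 untreated arrays per line and 3 per line at each treated time. The labels call the replicates biological and do not describe separate cultures, so p-values measure the spread between these samples, which may be technical. The authors' GCRMA intensities were taken to log2, and limma tested 12724 probe sets, the brightest standing for each of 7435 genes. Across probe sets, which are not independent replicates, arrays of a group correlated at r between 0.972 and 0.995. For arrays, the number of samples limits the precision.

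Log2 changes below carry the standard error of the limma fit, and group means carry the SD. Where a group mean lay under log2 5, a change is given as "at least" or as a bound, from the brighter mean to 5. The arrays of every group also split between 2 clusters when each array's deviation from its group mean was compared. Cluster 1 held 10 arrays, replicates 1 and 2 of the untreated groups and replicate 1 of each treated group, and cluster 2 held the other 16. The first axis of these deviations carried 38.8% of the variance within groups. Each of the 26 arrays correlated better with its own cluster (r 0.103 to 0.655) than with the other (-0.586 to 0.032). The Gapdh 3' minus 5' probe difference, a sign of RNA quality, was -0.146 ± 0.058 (SD, n = 10) in cluster 1 and 0.018 ± 0.094 (SD, n = 16) in cluster 2. Counts, the medians of a few lists and some single genes are therefore also given within each cluster. Cluster 1, with 1 treated array per group, left 2 residual degrees of freedom, and there the log2 value of 54 named calls moved by over 1.5 times (47 smaller, 7 larger), against 6 within cluster 2.

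**Figure D1:**
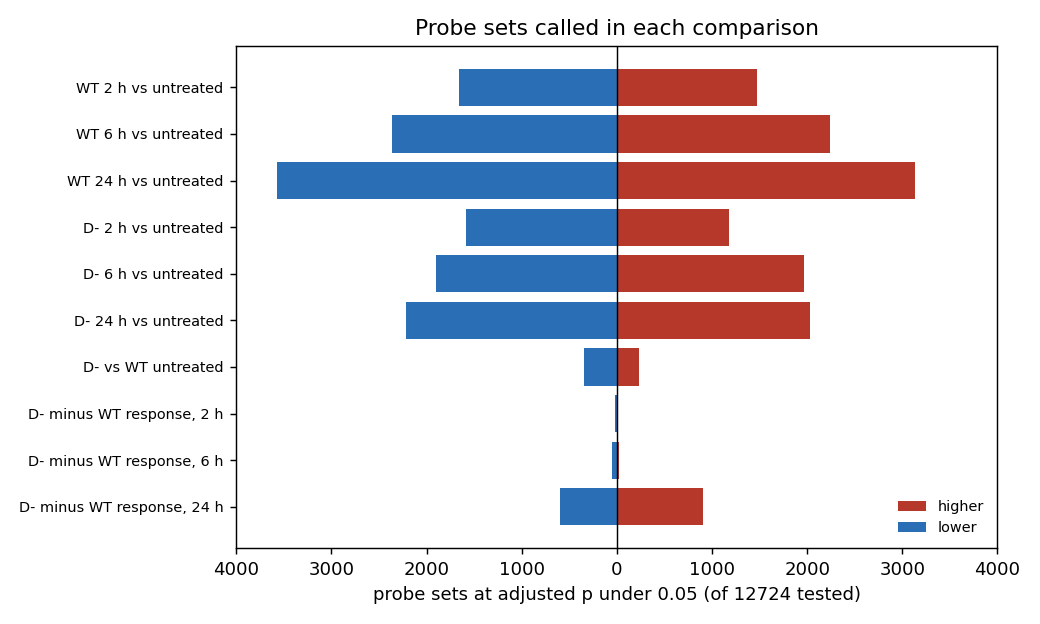
Number of probe sets at limma adjusted p under 0.05 in each of the 10 comparisons (horizontal axis, probe sets; higher to the right in red, lower to the left in blue). In WT cells 3136, 4601 and 6698 probe sets passed at 2, 6 and 24 h, in D- cells 2765, 3863 and 4250, and the response differed between the lines for 27, 66 and 1500.

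After 2 h, WT cells had strongly raised genes that cAMP is known to induce. Crem, which encodes a cAMP-responsive repressor, rose by at least 5.22 on the log2 scale, to 10.2 ± 0.83 (SD, n = 3, limma adjusted p = 1.04e-08). The immediate-early gene Fos rose by at least 4.33, the G protein signalling regulator Rgs2 by 5.52 ± 0.33, the nuclear receptor Nr4a1 by 4.22 ± 0.29 and the phosphatase gene Dusp1 by 4.22 ± 0.42. The thymocyte genes Ptcra, the pre-T cell receptor chain, and Rag1, the recombinase, fell, with log2 changes of -4.42 ± 0.47 and -2.66 ± 0.27, and so did Notch1 with -2.17 ± 0.34 and Bcl11b with -1.97 ± 0.17. Myc, a driver of growth, fell, with -2.49 ± 0.30 on the log2 scale.

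Among the lists fixed in advance, 11 of 17 measured CREB target genes rose at 2 h in WT (12 when adjusted over the list alone), with a median log2 change of 1.92. camera gave the list an adjusted p = 2.32e-10, and adjusted p = 0.00076 with an estimated correlation between genes. The feedback genes Per1 and Pde4b were among them, with 1.92 ± 0.31 and at least 1.64. Glucocorticoid-responsive genes rose in 8 of 16 cases and fell in 2 (10 and 2 adjusted over the list alone), with a median of 1.25 and camera adjusted p = 1.05e-05, but adjusted p = 0.0729 with an estimated correlation. Zfp36, an mRNA decay factor, rose by 3.85 ± 0.21 and Tsc22d3 by 2.26 ± 0.19. Cytokine receptor and JAK-STAT genes rose in 7 of 16 cases (also 7 adjusted over the list alone), with a median of 0.34, camera adjusted p = 0.00206, and adjusted p = 0.135 with an estimated correlation. The interferon gamma receptor genes Ifngr1 and Ifngr2 rose by 2.52 ± 0.19 and 2.52 ± 0.39, and Stat3 rose by 1.84 ± 0.28. T cell identity genes fell in 9 of 24 cases and rose in 3 (10 and 3 adjusted over the list alone), with a median of -0.24, camera adjusted p = 0.024 and adjusted p = 0.187 with an estimated correlation. Ribosome biogenesis and MYC target genes fell in 11 of 26 cases (also 11 adjusted over the list alone), with a median of -0.32, camera adjusted p = 0.000281 and adjusted p = 0.821 with an estimated correlation. The processing factors Ppan and Gnl3 showed -1.41 ± 0.27 and -1.16 ± 0.32. Of 22 measured pro-apoptotic genes 4 rose and 3 fell, with camera adjusted p = 0.52. Bcl2l11, which encodes the death protein BIM, rose by 1.72 ± 0.22 and Foxo1 by 2.46 ± 0.20, while Bid showed -1.87 ± 0.14. The survival gene Mcl1 rose by 0.71 ± 0.15, the CDK inhibitor Cdkn1b by 1.52 ± 0.30, the PKA regulatory subunit Prkar1a by 0.88 ± 0.10, the interferon regulator Irf1 by 2.45 ± 0.34, the glucose transporter Slc2a3 by 2.73 ± 0.31 and the hexokinase Hk2 by 1.16 ± 0.33. Bcl2, Prkaca, Ccnd3, Ccnd2 and Nr3c1 did not pass, with 0.19 ± 0.15, 0.26 ± 0.16, -0.24 ± 0.20, 0.28 ± 0.23 and 0.52 ± 0.24.

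limma called 3136 probe sets at 2 h in WT, 1472 higher and 1664 lower, of which 888 changed at least 2-fold. Higher calls were the more numerous with no filter on dim probe sets (1530 and 1505), without WT 2 h replicate 1 (1565 and 1449) and within cluster 1 (374 and 321). The count was 4081 with the cluster as a block, 3392 within cluster 2 and 695 within cluster 1, and the CREB list median was 1.84, 1.88 and 1.43 in the same order. The call for Gnl3 ended without WT 2 h replicate 3 (adjusted p = 0.0728), that for Hk2 without WT 2 h replicate 2 (0.0534) and within cluster 2 (0.0513), and Ccnd2 passed within cluster 2 (0.00426). Nr3c1 passed with the cluster as a block (0.00608), within cluster 2 (0.000444), with array weights (0.0269) and when only the groups compared were fitted (0.032).

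By 6 h, WT cells had lowered ribosome biogenesis genes almost throughout the list. Of 26 measured members 24 fell (25 adjusted over the list alone), with a median log2 change of -1.27, camera adjusted p = 1.04e-14, and adjusted p = 0.177 with an estimated correlation. The spermidine synthase gene Srm showed -2.51 ± 0.30, Ppan -1.9 ± 0.27 and the RNA polymerase I subunit Polr1b -1.65 ± 0.37. Rag1 had fallen from 11.6 ± 0.27 (SD, n = 4) to 6.13 ± 0.63 (SD, n = 3), a log2 change of -5.5 ± 0.27, and Ptcra showed -4.37 ± 0.47 and Rag2 -1.93 ± 0.27. Crem was still higher by at least 4.76 and Rgs2 by 4.44 ± 0.33.

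S phase genes had started to fall in WT at 6 h, in 10 of 31 cases with 1 rise (the same counts adjusted over the list alone). Their median was -0.38, with camera adjusted p = 0.0106 and adjusted p = 0.62 with an estimated correlation. Ung, a uracil glycosylase, fell with a log2 change of -2.54 ± 0.48, the thymidine kinase Tk1 with -1.11 ± 0.30, Uhrf1 with -1 ± 0.20 and Gins1 with -0.96 ± 0.31. The G1/S cyclins Ccne2 and Ccne1 showed -1.92 ± 0.32 and -1.38 ± 0.22, and Myc -2.11 ± 0.30. Mitosis genes instead rose in 10 of 31 cases (also 10 adjusted over the list alone), with a median of 0.26, camera adjusted p = 0.0197 and adjusted p = 0.62 with an estimated correlation. Among them were the phosphatases Cdc25b and Cdc25c, by 0.83 ± 0.12 and 0.75 ± 0.16, the kinase Ttk by 0.75 ± 0.20 and the kinetochore gene Cenpf by 0.83 ± 0.24. CREB targets rose in 7 of 17 cases (9 adjusted over the list alone), with a median of 0.76, camera adjusted p = 0.00119 and adjusted p = 0.147 with an estimated correlation. Glucocorticoid-responsive genes rose in 9 of 16 cases and fell in 1 (10 and 1 adjusted over the list alone), with a median of 0.83, camera adjusted p = 0.00119 and adjusted p = 0.177 with an estimated correlation. JAK-STAT genes rose in 9 of 16 cases and fell in 1 (the same adjusted over the list alone), with a median of 0.57, camera adjusted p = 0.00119 and adjusted p = 0.147 with an estimated correlation. Elsewhere, the guanylate-binding protein gene Gbp2 rose by at least 1.86, the chemokine receptor Ccr7 by at least 2.23, Pdcd4 by 1.86 ± 0.24, Bcl2l11 by 1.35 ± 0.22, Foxo1 by 2.09 ± 0.20, and the caspase inhibitor Cflar by 1.16 ± 0.19. Cdkn1b rose by 1.62 ± 0.30, Prkar1a by 1.36 ± 0.10, Nr4a1 by 2.22 ± 0.29, Tsc22d3 by 1.5 ± 0.19, the glucocorticoid receptor Nr3c1 by 0.76 ± 0.24 and the glucose transporter Slc2a1 by 1.47 ± 0.42. Ccr9 showed -2.04 ± 0.47 and the adhesion gene Cd2 -1.91 or lower. Bcl2, Mcl1, Per1, Prkaca and Ccnd3 did not pass, with 0.14 ± 0.15, 0.24 ± 0.15, 0.76 ± 0.31, 0.36 ± 0.16 and -0.30 ± 0.20, nor did Pde4b and Ccnd2, each with a group mean under 5.

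limma called 4601 probe sets at 6 h in WT, 2240 higher and 2361 lower, of which 1219 changed at least 2-fold. Without untreated WT replicate 3 (2179 and 2163) or WT 6 h replicate 1 (2327 and 2305) and within cluster 1 (733 and 627), the higher calls outnumbered the lower. With the cluster as a block 5516 passed, within cluster 2 4849 and within cluster 1 1360, and the list medians in that order were -1.26, -1.38 and -1.01 for ribosome biogenesis, -0.32, -0.45 and -0.29 for S phase and 0.29, 0.32 and 0.15 for mitosis. The mitosis call ended within cluster 1 (adjusted p = 0.134) and without WT 6 h replicate 2 (0.0603). Gins1, Nr3c1 and Cenpf lost their calls without WT 6 h replicate 2 (0.0712, 0.0719 and 0.0539) and without replicate 3 (0.0687, 0.0579 and 0.0671). Slc2a1 lost its call without WT 6 h replicate 1 (0.0544), with only the groups compared fitted (0.0827) and within cluster 2 (0.329), where its log2 change was 0.76, against 2.45 (0.0204) within cluster 1. Per1 and Prkaca passed with the cluster as a block (adjusted p = 0.0259 and 0.0245), within cluster 2 (0.00979 and 0.0326), with array weights (0.00403 and 0.0287) and with only the groups compared fitted (0.0193 and 0.0197). Per1 also passed without WT 6 h replicate 1 (0.0452), Ccnd3, lower, within cluster 2 (0.00443) and with array weights (0.0316), and Pde4b with only the groups compared fitted (0.00639).

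At 24 h, WT cells had lowered the genes of DNA replication and of mitosis together. All 31 measured S phase genes fell, with a median log2 change of -1.92 (camera adjusted p = 2.09e-15), and 29 of 31 mitosis genes fell and 1 rose, with a median of -1.57 (camera adjusted p = 8.89e-13). With an estimated correlation neither list kept its call (adjusted p = 0.151 and 0.149), and the counts were the same when adjusted over the list alone. The replication factors Cdc6 and Gins1 showed -2.8 ± 0.35 and -2.77 ± 0.31, Ung -3.25 ± 0.48 and Tk1 -2.66 ± 0.30. Aurkb, a mitotic kinase, showed -2.88 ± 0.24, the cyclins Ccna2 and Ccnf -2.29 ± 0.14 and -1.96 ± 0.18, and the checkpoint kinase Bub1 -1.98 ± 0.23. Over the same interval Bcl2l11 rose by 2.9 ± 0.22, from 9.06 ± 0.15 (SD, n = 4) to 12 ± 0.58 (SD, n = 3), with limma adjusted p = 8.73e-10.

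The Gapdh 3' minus 5' difference was 0.096 ± 0.195 (SD, n = 3) in the WT 24 h arrays against -0.053 ± 0.147 (SD, n = 4) in untreated WT. Of the G1 list, 10 of 22 genes fell and 4 rose (12 and 4 adjusted over the list alone), with camera adjusted p = 0.103. Ccne2 showed -3.64 ± 0.32, Ccnd3 -1.43 ± 0.20 and Myc -2.16 ± 0.30, while the MAX partner Mxd4 rose by 3.29 ± 0.26, the pocket protein gene Rbl2 by 2.1 ± 0.32 and Cdkn1b by 1.5 ± 0.30. All 26 ribosome biogenesis genes fell (also 26 adjusted over the list alone), with a median of -1.38, camera adjusted p = 3.13e-11 and adjusted p = 0.163 with an estimated correlation. Srm showed -2.58 ± 0.30, Nolc1 -2.08 ± 0.19 and Pa2g4 -2.08 ± 0.18. In the unfolded protein and amino acid stress list 11 of 22 genes fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.60, camera adjusted p = 0.00284 and adjusted p = 0.314 with an estimated correlation. Those that fell included the amino acid synthesis genes Psat1, Asns and Phgdh, with -2 ± 0.22, -1.67 ± 0.20 and -1.62 ± 0.28. Heat shock genes fell in 7 of 10 cases and rose in 1 (the same adjusted over the list alone), with a median of -0.46, camera adjusted p = 0.0214 and adjusted p = 0.134 with an estimated correlation. The chaperones Hsph1 and Hspd1 showed -1.52 ± 0.14 and -1.15 ± 0.11. Oxidative phosphorylation genes fell in 16 of 31 cases and rose in 1 (the same adjusted over the list alone), with a median of -0.24, camera adjusted p = 0.0273 and adjusted p = 0.314 with an estimated correlation. Ndufa5 showed -1.03 ± 0.14 and Ndufs1 -0.67 ± 0.10.

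Of the preset lists, 4 were raised by camera at 24 h in WT, none of them with an estimated correlation. JAK-STAT genes rose in 11 of 16 cases (12 adjusted over the list alone), with a median of 0.98, camera adjusted p = 3.17e-05 and adjusted p = 0.0874 with an estimated correlation. Ifngr1 rose by 3.3 ± 0.19, Jak2 by 2.22 ± 0.20 and Jak1 by 1.75 ± 0.15. CREB targets rose in 9 of 17 cases (10 adjusted over the list alone), with a median of 0.996, camera adjusted p = 0.00284 and adjusted p = 0.123 with an estimated correlation. Crem rose by at least 4.88 and Rgs2 by 4.78 ± 0.33. Glucocorticoid-responsive genes rose in 12 of 16 cases and fell in 1 (the same adjusted over the list alone), with a median of 1.18, camera adjusted p = 0.00198 and adjusted p = 0.149 with an estimated correlation. Txnip rose by 2.67 ± 0.44, Nr3c1 by 1.33 ± 0.24 and Tsc22d3 by 0.73 ± 0.19. Chemokine receptor and adhesion genes rose in 6 of 11 cases and fell in 1 (the same adjusted over the list alone), with a median of 0.81, camera adjusted p = 0.0273 and adjusted p = 0.123 with an estimated correlation. Ccr7 rose by at least 2.83, the selectin ligand Selplg by 2.33 ± 0.20 and Cxcr3 by 1.96 ± 0.51. Of the pro-apoptotic list 10 of 22 genes rose and 5 fell (camera adjusted p = 0.205), Pdcd4 rising by 2.6 ± 0.24, Foxo1 by 2.45 ± 0.20 and the granzyme Gzmb by at least 4.03. Of 16 anti-apoptotic genes 4 rose and 4 fell (camera adjusted p = 0.629), with Birc3 up by 1.92 ± 0.23 and Cflar by 1.46 ± 0.19. Of 15 p53 target genes 5 rose and 1 fell (camera adjusted p = 0.111), Trp53inp1 by 2.59 ± 0.28, Sesn1 by 2.2 ± 0.23 and Btg2 by 2.19 ± 0.26. Of 20 cAMP and PKA pathway genes 11 rose and 3 fell (camera adjusted p = 0.0899), among them the phosphodiesterase Pde1b by 2.32 ± 0.33, the cAMP-activated exchange factor Rapgef3 by 1.62 ± 0.32, Pde4b by at least 1.1 and Prkar1a by 0.86 ± 0.10. T cell identity genes rose in 9 of 24 cases and fell in 6 (camera adjusted p = 0.652), with Ptcra at -4.57 or lower, Rag1 at -4.43 ± 0.27, Gata3 at 1.79 ± 0.26 and the adaptor Lcp2 at 1.63 ± 0.20. Slc2a3 rose by 3.1 ± 0.31 and Nr4a1 by 0.84 ± 0.29. Bcl2, Mcl1, Per1, Prkaca and Ccnd2 did not pass, with 0.12 ± 0.15, 0.27 ± 0.15, 0.38 ± 0.31, -0.17 ± 0.16 and 0.12 ± 0.23.

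limma called 6698 probe sets at 24 h in WT, 3129 higher and 3569 lower, of which 2604 changed at least 2-fold (1293 higher, 1311 lower). Taking the cluster as a block, 7499 passed, within cluster 2 7026 and within cluster 1 3631, with list medians in that order of -1.87, -2.25 and -1.16 for S phase, -1.58, -1.84 and -1.09 for mitosis and -1.36, -1.53 and -1.02 for ribosome biogenesis. Nr4a1 lost its call without untreated WT replicate 3 (adjusted p = 0.0877, where its log2 change was 0.52), without WT 24 h replicate 3 (0.0527) and with only the groups compared fitted (0.0829), which also ended that of Cxcr3 (0.052), whose log2 change was 1.28 without WT 24 h replicate 2. Mcl1 passed when quantile normalization was added (adjusted p = 0.0303) and with the cluster as a block (0.0295). Ccnd2 passed with array weights (0.00279, log2 change 0.53), within cluster 2 (0.00231, log2 change 0.51) and without WT 24 h replicate 1 (0.0423). Within cluster 1 Cdc6 showed -1.49 and Myc -1.22.

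D- cells at 2 h had also raised genes that cAMP is known to induce. Crem rose by at least 5.31 on the log2 scale, to 10.3 ± 0.36 (SD, n = 3, limma adjusted p = 1.09e-08), Fos by at least 5.31, Rgs2 by 5.89 ± 0.33, Nr4a1 by 5.26 ± 0.29 and Dusp1 by 4.33 ± 0.42. Myc fell, with -3.16 ± 0.30 on the log2 scale, Rag1 showed -3.79 ± 0.27, Rag2 -3.21 ± 0.27, Ptcra -4.29 ± 0.47 and Notch1 -2.72 ± 0.34. Bcl2l11 rose by 1.49 ± 0.22, Foxo1 by 2.92 ± 0.20 and the killer-cell protease Gzmb by 6.45 ± 1.07.

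CREB targets rose in 11 of 17 cases at 2 h in D- (also 11 adjusted over the list alone), with a median of 2.15, camera adjusted p = 2.63e-12 and adjusted p = 0.000269 with an estimated correlation. Per1 rose by 2.49 ± 0.31 and Pde4b by 2.15 ± 0.34. Glucocorticoid-responsive genes rose in 9 of 16 cases and fell in 2 (10 and 2 adjusted over the list alone), with a median of 1.06, camera adjusted p = 1.23e-07 and adjusted p = 0.024 with an estimated correlation. Zfp36 rose by 3.86 ± 0.21 and Tsc22d3 by 2.23 ± 0.19. T cell identity genes fell in 11 of 24 cases and rose in 2 (the same adjusted over the list alone), with a median of -0.35, camera adjusted p = 0.00448 and adjusted p = 0.0823 with an estimated correlation. JAK-STAT genes rose in 5 of 16 cases and fell in 2 (5 and 3 adjusted over the list alone), with a median of 0.20, camera adjusted p = 0.0345 and adjusted p = 0.371 with an estimated correlation. Ifngr1 rose by 2.77 ± 0.19. Ribosome biogenesis genes fell in 6 of 26 cases (also 6 adjusted over the list alone), with a median of -0.26, camera adjusted p = 0.0181 and adjusted p = 0.61 with an estimated correlation. The p53 target list fell in 7 of 15 cases (8 lower and 2 higher adjusted over the list alone), with a median of -0.46, camera adjusted p = 0.0345 and adjusted p = 0.303 with an estimated correlation. The RNA-binding protein gene Zmat3 showed -0.97 ± 0.21 and the death receptor Fas -0.92 ± 0.30. In the unfolded protein and amino acid stress list 4 of 22 genes rose (also 4 adjusted over the list alone), with a median of 0.25, camera adjusted p = 0.0181 and adjusted p = 0.61 with an estimated correlation. The stress factor Ddit3 rose by 1.54 ± 0.27 and Herpud1 by 0.92 ± 0.26. Cholesterol genes rose in 5 of 18 cases (6 adjusted over the list alone), with a median of 0.19, camera adjusted p = 0.0345 and adjusted p = 0.61 with an estimated correlation. The sterol carrier Stard4 rose by 1.43 ± 0.23 and the demethylase Cyp51 by 1.3 ± 0.35. Mcl1 rose by 0.76 ± 0.15, Cdkn1b by 1.32 ± 0.30, Prkar1a by 0.88 ± 0.10 and Slc2a3 by 3.19 ± 0.31, and Bid showed -2.16 ± 0.14. Bcl2, Prkaca, Ccnd3, Ccnd2 and Nr3c1 did not pass, with 0.34 ± 0.15, 0.15 ± 0.16, -0.36 ± 0.20, 0.29 ± 0.23 and 0.53 ± 0.24.

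limma called 2765 probe sets at 2 h in D-, 1182 higher and 1583 lower, of which 799 changed at least 2-fold. After median centring of the arrays the balance turned, to 1413 higher and 1295 lower (52.2% higher against 42.7%), as it did within cluster 1 (387 and 379). With the cluster as a block 3660 passed, within cluster 2 2772 and within cluster 1 766, and the CREB list median was 2.15, 1.97 and 2.66 in that order. The call for Cyp51 ended without D- 2 h replicate 3 (adjusted p = 0.0591), and that for Herpud1 without D- 2 h replicate 2 (0.0617). Fas lost its call without untreated D- replicate 1, 2 or 3 or D- 2 h replicate 2 or 3 (at most 0.172, without the last of these) and with no filter (0.0613). Nr3c1 passed with the cluster as a block (0.00629), within cluster 2 (0.00721) and with array weights (0.0487), and without D- 2 h replicate 1 both Nr3c1 (0.0383) and Ccnd3 (0.0437) passed.

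By 6 h, ribosome biogenesis genes had fallen in D- too, in 24 of 26 cases (also 24 adjusted over the list alone), with a median of -1.03, camera adjusted p = 2.51e-13 and adjusted p = 0.168 with an estimated correlation. Srm showed -2.22 ± 0.30, Rrp12 -1.68 ± 0.27 and Ppan -1.5 ± 0.27. S phase genes fell in 14 of 31 cases (also 14 adjusted over the list alone), with a median of -0.46, camera adjusted p = 0.000222 and adjusted p = 0.585 with an estimated correlation. Ung showed -2.31 ± 0.48, Gins1 -1.27 ± 0.31, Tk1 -1.04 ± 0.30 and Mcm10 -1.01 ± 0.22. Of 31 mitosis genes 2 rose and 1 fell, with a median of 0.13 (camera adjusted p = 0.299), Ttk with 0.86 ± 0.20 and Bub1b with -0.70 ± 0.19.

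CREB targets rose in 11 of 17 cases at 6 h in D- (11 higher and 1 lower adjusted over the list alone), with a median of 1.25, camera adjusted p = 9.24e-05 and adjusted p = 0.0471 with an estimated correlation. Crem rose by at least 3.77, Rgs2 by 4.4 ± 0.33, Nr4a1 by 3.18 ± 0.29, Per1 by 1.25 ± 0.31 and Pde4b by 1.18 ± 0.34. Glucocorticoid-responsive genes rose in 10 of 16 cases and fell in 1 (the same adjusted over the list alone), with a median of 0.95, camera adjusted p = 0.000222 and adjusted p = 0.168 with an estimated correlation. Tsc22d3 rose by 1.46 ± 0.19 and Nr3c1 by 0.81 ± 0.24. JAK-STAT genes rose in 7 of 16 cases and fell in 1 (the same adjusted over the list alone), with a median of 0.39, camera adjusted p = 0.00577 and adjusted p = 0.168 with an estimated correlation. Ifngr1 rose by 2.61 ± 0.19 and Jak2 by 1.96 ± 0.20. T cell identity genes fell in 11 of 24 cases and rose in 3 (the same adjusted over the list alone), with a median of -0.19, camera adjusted p = 0.0151 and adjusted p = 0.168 with an estimated correlation. Rag1 showed -4.09 ± 0.27 and Ptcra -6.24 ± 0.47. Gzmb rose by 7.25 ± 1.07, Pdcd4 by 1.59 ± 0.24, Bcl2l11 by 0.88 ± 0.22, Cflar by 0.86 ± 0.19, Cdkn1b by 1.31 ± 0.30, Prkar1a by 1.28 ± 0.10 and the PKA catalytic subunit Prkaca by 0.42 ± 0.16. The cyclins Ccne1 and Ccne2 showed -1.69 ± 0.22 and -1.42 ± 0.32, and Myc -1.65 ± 0.30. Bcl2, Mcl1 and Ccnd3 did not pass, with 0.23 ± 0.15, 0.24 ± 0.15 and -0.033 ± 0.20, nor did Ccnd2, whose mean at 6 h lay under 5.

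limma called 3863 probe sets at 6 h in D-, 1963 higher and 1900 lower, of which 928 changed at least 2-fold. Lower calls were the more numerous after median centring (1827 higher and 2111 lower), after quantile normalization (1904 and 2026) and with the cluster as a block (2389 and 2400). Taking the cluster as a block, 4789 passed, within cluster 2 4321 and within cluster 1 837, with medians in that order of -0.99, -1.13 and -0.85 for ribosome biogenesis and -0.42, -0.44 and -0.42 for S phase. The call for Tk1 ended without D- 6 h replicate 2 (adjusted p = 0.067), that for Nr3c1 without D- 6 h replicate 2 (0.0697) or 3 (0.0587), and that for Pde4b without D- 6 h replicate 3 (0.0914). Prkaca lost its call without untreated D- replicate 1 or 2 or D- 6 h replicate 2 or 3 (at most 0.263, without the last of these) and after median centring of the arrays (0.0757). It also lost it after quantile normalization (0.0551), with no filter (0.0771) and with only the groups compared fitted (0.143).

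At 24 h, few S phase or mitosis genes had changed in D- cells. Of 31 S phase genes 2 fell and 1 rose (the same adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.0879). Of 31 mitosis genes 6 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.0879). Mcm10 showed -0.81 ± 0.22, Ccna2 -0.67 ± 0.14, Hmmr -0.81 ± 0.22 and Aurkb -0.72 ± 0.24. Ribosome biogenesis genes had fallen in 25 of 26 cases (26 adjusted over the list alone), with a median of -1.05, camera adjusted p = 7.84e-13 and adjusted p = 0.182 with an estimated correlation. Srm showed -2.01 ± 0.30, Polr1b -1.58 ± 0.37 and Ppan -1.47 ± 0.27.

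JAK-STAT genes rose in 9 of 16 cases at 24 h in D- (also 9 adjusted over the list alone), with a median of 0.76, camera adjusted p = 4.63e-05 and adjusted p = 0.075 with an estimated correlation. Ifngr1 rose by 2.81 ± 0.19 and Jak2 by 2.59 ± 0.20. Glucocorticoid-responsive genes rose in 11 of 16 cases (also 11 adjusted over the list alone), with a median of 1.2, camera adjusted p = 4.63e-05 and adjusted p = 0.0754 with an estimated correlation. Txnip rose by 2.21 ± 0.44, Nr3c1 by 1.47 ± 0.24 and Tsc22d3 by 0.77 ± 0.19. CREB targets rose in 9 of 17 cases and fell in 1 (10 and 2 adjusted over the list alone), with a median of 1.12, camera adjusted p = 0.000797 and adjusted p = 0.075 with an estimated correlation. Crem rose by at least 2.27, Rgs2 by 4.65 ± 0.33, Nr4a1 by 2.33 ± 0.29 and Per1 by 1.12 ± 0.31. Pro-apoptotic genes rose in 8 of 22 cases and fell in 3 (9 and 3 adjusted over the list alone), with a median of 0.24, camera adjusted p = 0.0252 and adjusted p = 0.213 with an estimated correlation. Gzmb rose by 5.3 ± 1.07, Pdcd4 by 2.72 ± 0.24, the forkhead factors Foxo1 and Foxo3 by 2.11 ± 0.20 and 1.83 ± 0.17, and Bcl2l11 by 1.27 ± 0.22. In the unfolded protein and amino acid stress list 9 of 22 genes fell and 1 rose (the same adjusted over the list alone), with a median of -0.42, camera adjusted p = 0.0252 and adjusted p = 0.581 with an estimated correlation. Phgdh showed -1.2 ± 0.28 and Asns -1 ± 0.20. Of the G1 list 5 of 22 genes rose and 5 fell (camera adjusted p = 0.903), Mxd4 with 2.58 ± 0.26, Rbl2 with 1.79 ± 0.32, Cdkn1b with 1.12 ± 0.30, Ccne1 with -1.94 ± 0.22 and Myc with -1.52 ± 0.30. T cell identity genes rose in 6 of 24 cases and fell in 3 (camera adjusted p = 0.0879), with Ptcra at -4.46 ± 0.47, Rag2 at -2.59 ± 0.27, Rag1 at -1.54 ± 0.27, Gata3 at 2.26 ± 0.26 and Ets1 at 1.71 ± 0.18. The adhesion genes Selplg and Itgb2 rose by 2.59 ± 0.20 and 1.53 ± 0.13, Cflar by 1.1 ± 0.19, Mcl1 by 0.62 ± 0.15, Prkar1a by 0.90 ± 0.10 and the myeloid integrin Itgam by at least 0.83. Itgal also passed, with both means under 5. Bcl2, Pde4b, Prkaca and Ccnd3 did not pass, with 0.16 ± 0.15, 0.34 ± 0.34, 0.12 ± 0.16 and -0.35 ± 0.20, nor did Ccnd2, whose mean at 24 h lay under 5.

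limma called 4250 probe sets at 24 h in D-, 2033 higher and 2217 lower, of which 1132 changed at least 2-fold (727 higher, 405 lower). More were higher than lower within cluster 2 (2584 and 2496), within cluster 1 (482 and 344) and without D- 24 h replicate 2 (1584 and 1500). With the cluster as a block 5249 passed, within cluster 2 5080 and within cluster 1 826, with medians in that order of -1.01, -1.24 and -0.63 for ribosome biogenesis, -0.19, -0.32 (camera adjusted p = 0.00942) and -0.056 for S phase and -0.20, -0.21 and -0.17 (0.0245) for mitosis. The S phase list also passed without D- 24 h replicate 1 (median -0.41, adjusted p = 0.0174), and its median was -0.11 without D- 24 h replicate 2. Leaving out D- 24 h replicate 2 ended the calls for Mcm10 (0.0622), Hmmr (0.0516), Itgam (0.0827), Per1 (0.0733) and Aurkb (0.136). That for Aurkb also ended without untreated D- replicate 1 (0.0612) or 2 (0.0536), without D- 24 h replicate 3 (0.0858) and with no filter (0.0501). Itgam did not pass with only the groups compared fitted (0.0555), nor Hmmr within cluster 2 (0.077). Within cluster 1 Bcl2l11 (0.62, 0.178), Gzmb (3.52, 0.459), Cdkn1b (0.72, 0.177) and Per1 (0.40, 0.183) did not pass.

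**Figure D2:**
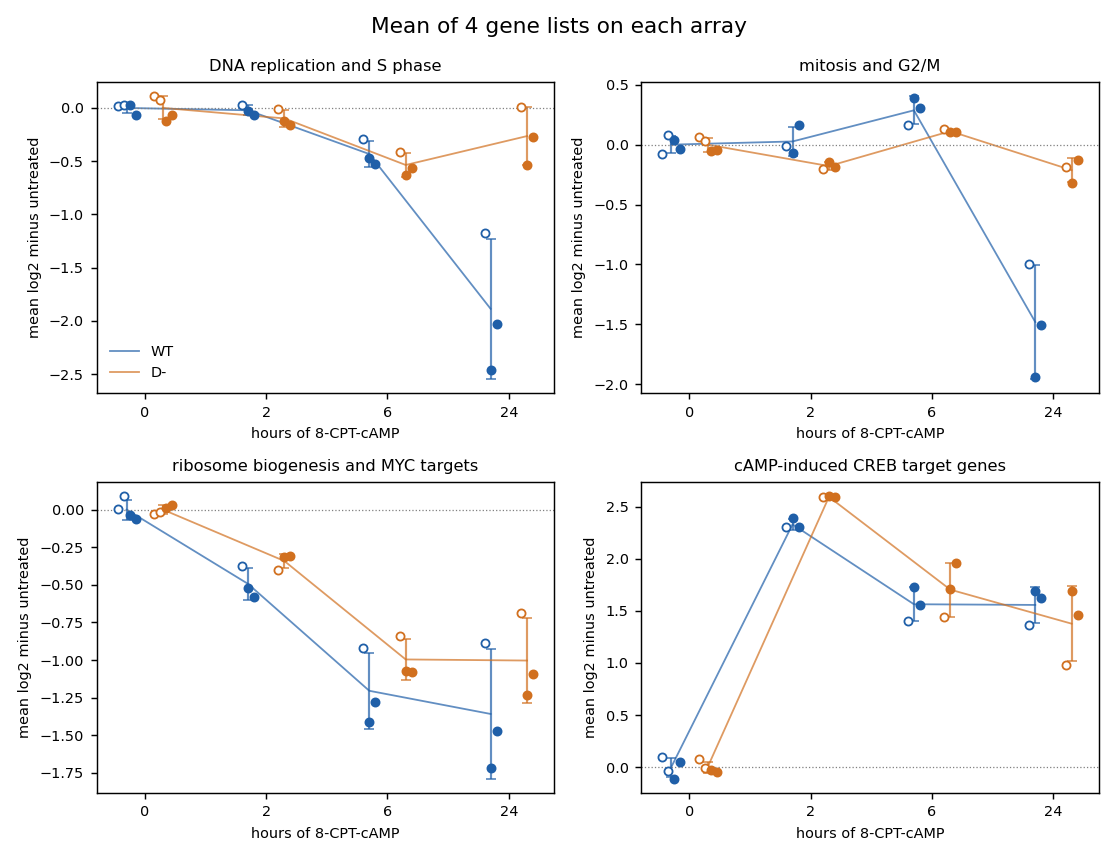
Mean log2 change of each array from the untreated mean of its line (vertical axis) against hours of 8-CPT-cAMP (horizontal axis) for 4 gene lists: S phase, mitosis, ribosome biogenesis and CREB targets. WT arrays are blue and D- arrays orange, open circles are cluster 1 arrays and filled circles cluster 2 arrays, and bars show the mean ± SD. At 24 h the S phase mean was -1.89 ± 0.66 in WT and -0.26 ± 0.27 in D- (n = 3 each).

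Untreated D- cells differed from untreated WT cells in 577 of 12724 probe sets. Ifitm2, an interferon-induced membrane protein gene, was lower in D- by a log2 difference of -4.87 or lower, and so were the T cell receptor zeta chain Cd247 (-4.34 or lower), the leukocyte actin-binding protein gene Lsp1 (-3.98 or lower) and Dock2, a guanine nucleotide exchange factor of lymphocyte migration (-3.24 or lower). The galectin gene Lgals9 showed -4.32 ± 0.16. Higher in D- were Cd2, a T cell adhesion receptor, by 3.74 ± 0.27, Ptcra by 2.05 ± 0.44 and Rag2 by 1.44 ± 0.25.

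Of 24 T cell identity genes 4 were higher and 4 lower in untreated D- (5 and 6 adjusted over the list alone), with camera adjusted p = 0.841. Further lower genes in D- were Dppa4 (-3.12 or lower), Naip5 (-0.51 or lower), Plac8 with -3.33 ± 0.92 and Trat1, a T cell receptor adaptor, with -3.06 ± 0.52. The kinase Pim1 was lower with -1.01 ± 0.18, as was Bub1b with -0.67 ± 0.17, and so were the leukocyte integrins Itgb2 with -0.80 ± 0.12 and Itgal (-0.33 or lower). Further higher genes were Slfn4 by at least 3.89, Amot by at least 4.2, Rgl3 by 4.28 ± 0.49 and Acot1 by 3.56 ± 0.47. So were the gap junction gene Gja1 by at least 0.83, the p53 targets Btg2 and Zmat3 by 1.34 ± 0.24 and 0.98 ± 0.19, and the PKA inhibitor gene Pkig by 0.89 ± 0.20. Mitosis genes as a list were higher in D- (median 0.19, camera adjusted p = 0.00228, adjusted p = 0.928 with an estimated correlation), while 1 of its 31 genes passed on its own, Bub1b, in the other direction. Genes fixed in advance that did not pass were Bcl2l11 (0.38 ± 0.20), Bcl2 (0.18 ± 0.14), Mcl1 (0.058 ± 0.14), Nr4a1 (-0.78 ± 0.27) and Per1 (-0.14 ± 0.29). Neither did Prkar1a (-0.094 ± 0.10), Prkaca (-0.089 ± 0.15), Ccnd3 (-0.34 ± 0.18), Ccnd2 (0.015 ± 0.22), Cdkn1b (0.36 ± 0.28), Myc (0.072 ± 0.28), Rag1 (0.30 ± 0.25), Tsc22d3 (0.36 ± 0.18) or Nr3c1 (0.14 ± 0.22) pass, nor Crem and Pde4b, whose WT means lay under 5.

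limma called 577 probe sets between the untreated lines, 228 higher and 349 lower in D-, of which 185 differed at least 2-fold (84 higher, 101 lower). Taking the cluster as a block, 943 passed, within cluster 2 889 and within cluster 1 67 (35 higher, 32 lower), with array weights 1050, and 380 passed without untreated D- replicate 4. The call for Plac8 ended without untreated D- replicate 1 or 2 or WT replicate 1, 2 or 4 (at most adjusted p = 0.171, without D- replicate 2) and within cluster 2 (0.551), where its difference was -0.32, against -6.34 (0.00333) within cluster 1. It also ended with no filter (0.0835), with array weights (0.0737) and with only the groups compared fitted (0.163). That for Bub1b ended without D- replicate 1, 2 or 4 or WT replicate 2, 3 or 4 (at most 0.0932, without WT replicate 3) and within cluster 2 (0.0784), and that for Pkig without WT replicate 3 (0.0544), where Nr4a1 passed (0.00776). Within cluster 2 Ccnd3 passed, with a difference of -0.79 (0.00377), and Nr3c1 with 0.42 (0.0221). Of the 185 probe sets, 173 differed in the same direction at all 3 treated times, 95 of them at least 2-fold, and 125 differed at least 2-fold within both clusters.

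The responses of the lines, which have separate untreated arrays, were compared next. Across probe sets, the WT and D- log2 changes correlated at Pearson r 0.872, 0.874 and 0.787 (Spearman rho 0.793, 0.858 and 0.785) at 2, 6 and 24 h. At 24 h 1647 probe sets were higher and 1865 lower in both lines and 57 moved in opposite directions, against 500 and 622 for independent lists. At 2 h 917 were higher and 1120 lower in both and 1 was opposite (137 and 207 for independent lists), and at 6 h 1489 and 1602, with 5 opposite (346 and 353 for independent lists). Over the 3863, 5368 and 7379 probe sets called in either line, the principal axis of D- against WT changes had a slope of 0.971, 0.896 and 0.66. Within cluster 2 r was 0.833 at 2 h and 0.821 at 6 h, and within cluster 1 it was 0.796, 0.805 and 0.66, and without WT 2 h replicate 1 it was 0.835 at 2 h.

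At 2 h the response to cAMP differed between the lines for 27 of 12724 probe sets. An unadjusted limma p under 0.05 was reached by 737, where chance alone would give 636. The adaptor gene Grb7 rose in D- by at least 3.01 and its D- minus WT difference of response was 4.64 ± 0.37 (limma adjusted p = 2.4e-07), with 3.05 ± 0.25 for the OX40 ligand Tnfsf4 and 2.58 ± 0.40 for Palld, an actin-associated protein gene. In the other direction were C4bp with -2.76 ± 0.33, Ctla2a, a cysteine protease inhibitor gene, with -2.48 ± 0.50, Sgip1 with -2.26 ± 0.41 and the lymphocyte receptor Slamf1 with -1.83 ± 0.37. Apart from Palld and Slamf1 these genes had a group mean under 5, so their differences are fitted values and no measure of fold. By list, mitosis genes lay lower in D- (median -0.19, camera adjusted p = 0.0205, adjusted p = 0.674 with an estimated correlation), and ribosome biogenesis genes (0.13, 0.0205) and stress genes (0.16, 0.0205) higher, with adjusted p = 0.674 and 0.538 with an estimated correlation. Among genes fixed in advance differences that did not pass were those of Rag1 with -1.12 ± 0.38 (adjusted p = 0.447), Nr4a1 with 1.04 ± 0.41 (0.683), Myc with -0.67 ± 0.43 (0.999) and Per1 with 0.57 ± 0.44 (0.999), and Bcl2l11 showed -0.23 ± 0.31 (0.999). Bcl2, Mcl1, Crem, Pde4b, Prkar1a, Prkaca, Ccnd3, Ccnd2, Cdkn1b, Tsc22d3 and Nr3c1 lay between -0.20 for Cdkn1b and 0.22 for Pde4b, each with adjusted p = 0.999.

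limma called 27 probe sets, 5 higher and 22 lower in D-, of which 16 had the smaller response in D-. The count was 71 with the cluster as a block, 96 within cluster 2, 1, a higher one, within cluster 1, 110 with array weights (18 higher, 92 lower) and 16 with only the groups compared fitted. It was 16 and 15 without untreated D- replicates 1 and 2, 11 without D- 2 h replicate 2 or 3, 17 without untreated WT replicate 1 and 49, 8 and 7 without WT 2 h replicates 1, 2 and 3, the 7 being 4 higher and 3 lower. Ctla2a and Slamf1 lost their calls without any 1 untreated array except WT replicate 3, and without replicate 2 or 3 of either line at 2 h (at most adjusted p = 0.156 and 0.139, both without WT 2 h replicate 3). Slamf1 also lost it without D- 2 h replicate 1 (0.0823), and both with no filter (0.0727 and 0.0655). Sgip1 lost its call without D- 2 h replicate 3 (0.0677) and WT 2 h replicates 2 (0.0798) and 3 (0.0768), and with only the groups compared fitted neither Sgip1 (0.084) nor Ctla2a (0.102) passed. In 7 of 100 regroupings, the real one included, at least as many probe sets passed.

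At 6 h the response differed between the lines for 66 probe sets. Ctla4, a brake on T cell activation, had a D- minus WT difference of response of -3.49 ± 0.55 (limma adjusted p = 0.00202), and the kinase gene Prkcq of T cell receptor signalling -2.09 ± 0.41. Ctla2b averaged 7.63 ± 0.34 (SD, n = 3) in WT against a D- mean under 5, a fitted difference of response of -4.22 ± 0.37. Further differences were 4.44 ± 0.47 for the sulfotransferase Chst1, 3.03 ± 0.40 for Ifitm2, 3.03 ± 0.37 for Grb7, -3.07 ± 0.50 for Ctla2a, -3.03 ± 0.33 for C4bp, -2.4 ± 0.41 for Sgip1, -2.15 ± 0.49 for the growth factor receptor Pdgfrb and -0.69 ± 0.16 for Stat5b. Of these, only Ctla4, Prkcq and Stat5b had all group means over 5. Heat shock genes as a list lay higher in D- (median 0.24, camera adjusted p = 0.000578, adjusted p = 0.0241 with an estimated correlation), though 2 of its 10 genes passed only when adjusted over the list alone. Mitosis genes lay lower (-0.14, camera adjusted p = 0.0106, adjusted p = 0.922 with an estimated correlation) and ribosome biogenesis genes higher (0.22, 0.00785, adjusted p = 0.922 with an estimated correlation). Rag1 did not pass, with 1.41 ± 0.38 (adjusted p = 0.13), nor did Nr4a1 with 0.96 ± 0.41 (0.661) or Bcl2l11 with -0.47 ± 0.31 (0.995), and Rag1 passed within cluster 2 (0.0216), with array weights (0.00316) and without WT 6 h replicate 1 (0.0118). Crem showed -1.11 ± 0.71, Pde4b 0.64 ± 0.49, Per1 0.49 ± 0.44, Myc 0.47 ± 0.43, Cdkn1b -0.31 ± 0.42 and Ccnd3 0.27 ± 0.28, and Bcl2, Mcl1, Prkar1a, Prkaca, Ccnd2, Tsc22d3 and Nr3c1 lay between -0.073 for Prkar1a and 0.081 for Bcl2, without passing.

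limma called 66 probe sets at 6 h, 18 higher and 48 lower in D-, of which 43 had the smaller response in D-. The count was 138 with the cluster as a block, 215 within cluster 2, 0 within cluster 1 (limma, 776 at an unadjusted p under 0.05) and 353 with array weights (162 higher, 191 lower). It was 43 and 42 without D- 6 h replicates 2 and 3 and 110, 35 and 43 without WT 6 h replicates 1, 2 and 3. Pdgfrb lost its call without any 1 of the 14 arrays except D- 6 h replicate 2 (at most adjusted p = 0.158, without D- 6 h replicate 1), and Stat5b except untreated D- replicate 3 (at most 0.204, without WT 6 h replicate 2). Both also lost it after quantile normalization (0.0584 and 0.0623) and with no filter (0.0897 and 0.0512), and Stat5b after median centring (0.0934) and with the filter at log2 7 (0.0506). Prkcq lost its call without D- 6 h replicate 3 (0.076) and WT 6 h replicates 2 (0.0649) and 3 (0.0516). Pdgfrb, Stat5b and Prkcq did not pass with only the groups compared fitted (0.0806, 0.0595 and 0.0596), and within cluster 2 Pdgfrb (0.134), Stat5b (0.0994) and Prkcq (0.0634) did not pass. At least as many probe sets passed in 6 of 100 regroupings, the real one included.

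At 24 h the lines differed in cell cycle genes, which had fallen further in WT. Of 31 S phase genes 30 had a response higher in D- (31 adjusted over the list alone), with a median D- minus WT difference of 1.62 on the log2 scale. So had 27 of 31 mitosis genes (28 adjusted over the list alone), with a median of 1.37. camera gave adjusted p = 1.04e-29 for the S phase and 1.22e-23 for the mitosis list, and adjusted p = 0.0957 for each with an estimated correlation. The difference was 2.38 ± 0.43 for Tk1, 2.34 ± 0.50 for Cdc6, 2.23 ± 0.31 for the helicase component Cdc45 and 2.15 ± 0.68 for Ung, and outside the lists it was 2.39 ± 0.42 for the checkpoint kinase Chek1. Among mitosis genes it was 2.16 ± 0.35 for Aurkb, 1.96 ± 0.28 for Ttk, 1.72 ± 0.31 for the spindle gene Prc1 and 1.63 ± 0.49 for the motor gene Cenpe. Bcl2l11 rose further in WT than in D-, with a difference of -1.62 ± 0.31 (limma adjusted p = 0.0012).

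Over whole arrays, the list mean differed between the lines by 1.62 for S phase and 1.27 for mitosis, each with an exact permutation p = 0.1 (two-sided), the smallest that 3 against 3 arrays allow. For ribosome biogenesis and CREB targets the array means differed by 0.36 and -0.18 (exact permutation p = 0.3 and 0.7). In the G1 list 4 of 22 genes were higher in D- (camera adjusted p = 0.0674), Ccne2 with 2.18 ± 0.45, Cdk2 with 1.2 ± 0.20, Ccnd3 with 1.07 ± 0.28 and E2f1 with 1.04 ± 0.19. p53 targets lay lower in D- in 3 of 15 cases (6 adjusted over the list alone), with a median of -0.30, camera adjusted p = 0.0226 and adjusted p = 0.223 with an estimated correlation. Trp53inp1 showed -1.4 ± 0.40, Sesn1 -1.17 ± 0.33 and Zmat3 -1.16 ± 0.29. Ribosome biogenesis genes lay higher in D-, with a median of 0.32 and 2 of 26 genes passing (also 2 adjusted over the list alone), Nolc1 with 1 ± 0.27 and Pa2g4 with 0.92 ± 0.26, camera adjusted p = 0.0209 and adjusted p = 0.637 with an estimated correlation. In the T cell list 2 of 24 genes were higher and 2 lower, among them Rag1 with 2.89 ± 0.38, Bcl11b with 1.36 ± 0.24 and Lcp2 with -1.22 ± 0.28. In the CREB list Nr4a1 was higher in D- with 1.49 ± 0.41, and Junb with -1.77 ± 0.55 and Crem with -2.73 ± 0.71 were lower. Single genes of other lists were Birc3 with -1.45 ± 0.33, Pde1b with -1.51 ± 0.47, Fkbp5 with 1.67 ± 0.28, Psat1 with 1.11 ± 0.31, the lactate transporter Slc16a1 with 0.85 ± 0.24, Hsph1 with 0.84 ± 0.20 and Dnajb1 with 0.61 ± 0.16. Among genes with a group mean under 5, whose differences are fitted values, were Ccr7 with -2.92 ± 0.41, Ctla2b with -6.47 ± 0.37, Ctla2a with -4.89 ± 0.50, the nuclear receptor Pparg with -3.95 ± 0.33, Naip5 with -3.62 ± 0.80 and the chemokine receptor Cxcr6 with -3.2 ± 0.92. Bcl2, Mcl1, Per1, Prkar1a, Prkaca, Cdkn1b, Myc, Tsc22d3 and Nr3c1 did not pass, with 0.048 ± 0.22, 0.35 ± 0.21, 0.75 ± 0.44, 0.035 ± 0.14, 0.29 ± 0.23, -0.39 ± 0.42, 0.64 ± 0.43, 0.047 ± 0.27 and 0.14 ± 0.33. Pde4b with -1.04 ± 0.49 and Ccnd2 with -0.14 ± 0.33, each with a group mean under 5, did not pass either.

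limma called 1500 probe sets at 24 h, 903 higher and 597 lower in D-, and 747 differed at least 2-fold (452 higher, 295 lower). In 1287 of the 1500, 85.8%, the response was smaller in D-. Of the 1500, 815 were called in WT and not in D-, 112 in D- and not in WT, 506 in both in the same direction, 57 in opposite directions and 10 in neither. With the cluster as a block 2565 passed, within cluster 2 2277 and within cluster 1 5 (1 higher, 4 lower), with medians in that order of 1.62, 1.91 and 1.10 for the S phase and 1.37, 1.65 and 0.81 for the mitosis list. The count was 3084 with array weights, 2352 without WT 24 h replicate 1 and 962 without WT 24 h replicate 2. Without that second array the calls ended for Ccnd3 (adjusted p = 0.0527), Cenpe (0.132), Crem (0.0507), Cxcr6 (0.107), Junb (0.15), Nolc1 (0.0726), Pa2g4 (0.0891), Pde1b (0.132), Psat1 (0.0871), Sesn1 (0.0929), Slc16a1 (0.0507), Trp53inp1 (0.0851) and Ung (0.163). Without D- 24 h replicate 1 those for Ccnd3 (0.056), Cenpe (0.0612), Cxcr6 (0.0954), Junb (0.0617), Nolc1 (0.0591), Pa2g4 (0.0548), Pde1b (0.138), Psat1 (0.058), Sesn1 (0.0838), Trp53inp1 (0.0787) and Ung (0.128) ended, and Per1 passed (0.042). Without WT 24 h replicate 3 those for Cenpe (0.0584), Cxcr6 (0.0868), Junb (0.109), Nolc1 (0.0654), Pa2g4 (0.066), Pde1b (0.0866), Psat1 (0.0699), Sesn1 (0.0664) and Ung (0.126) ended. D- 24 h replicate 2 left out ended that for Cenpe (0.0668), and replicate 3 those for Cxcr6 (0.0535), Junb (0.094), Slc16a1 (0.074) and Ung (0.0537). Among untreated arrays left out singly, D- replicate 3 and WT replicates 2 and 4 ended the call for Cenpe (at most 0.0665) and D- replicate 3 that for Cxcr6 (0.0501). D- replicates 1, 2 and 3 and all 4 WT replicates ended that for Junb (at most 0.0702). D- replicates 1, 2 and 3 and WT replicates 1 and 2 ended that for Pde1b (at most 0.0723), and D- replicates 1, 3 and 4 and WT replicates 1 and 2 that for Ung (at most 0.0811). With no filter on dim probe sets Ung (0.0799), Cenpe (0.059), Junb (0.0705) and Pde1b (0.0705) did not pass. When only the groups compared were fitted those 4 (0.0756, 0.0702, 0.0555 and 0.103), Nr4a1 (0.0509), Trp53inp1 (0.0721), Sesn1 (0.0776), Cxcr6 (0.0884), Nolc1 (0.0562) and Psat1 (0.0884) did not pass. Within cluster 2 Crem (0.0712), Nr4a1 (0.118) and Zmat3 (0.0938) did not pass, and Pde1b and Naip5 showed -0.82 and -2.2. Myc passed there, with a difference of 0.89 (0.0303), and so did Ccnd2, with a fitted value of -0.57 (0.0293). Mcl1 passed with the cluster as a block (0.0412). In 13 of 100 regroupings, the real one included, at least as many probe sets passed.

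**Figure D3:**
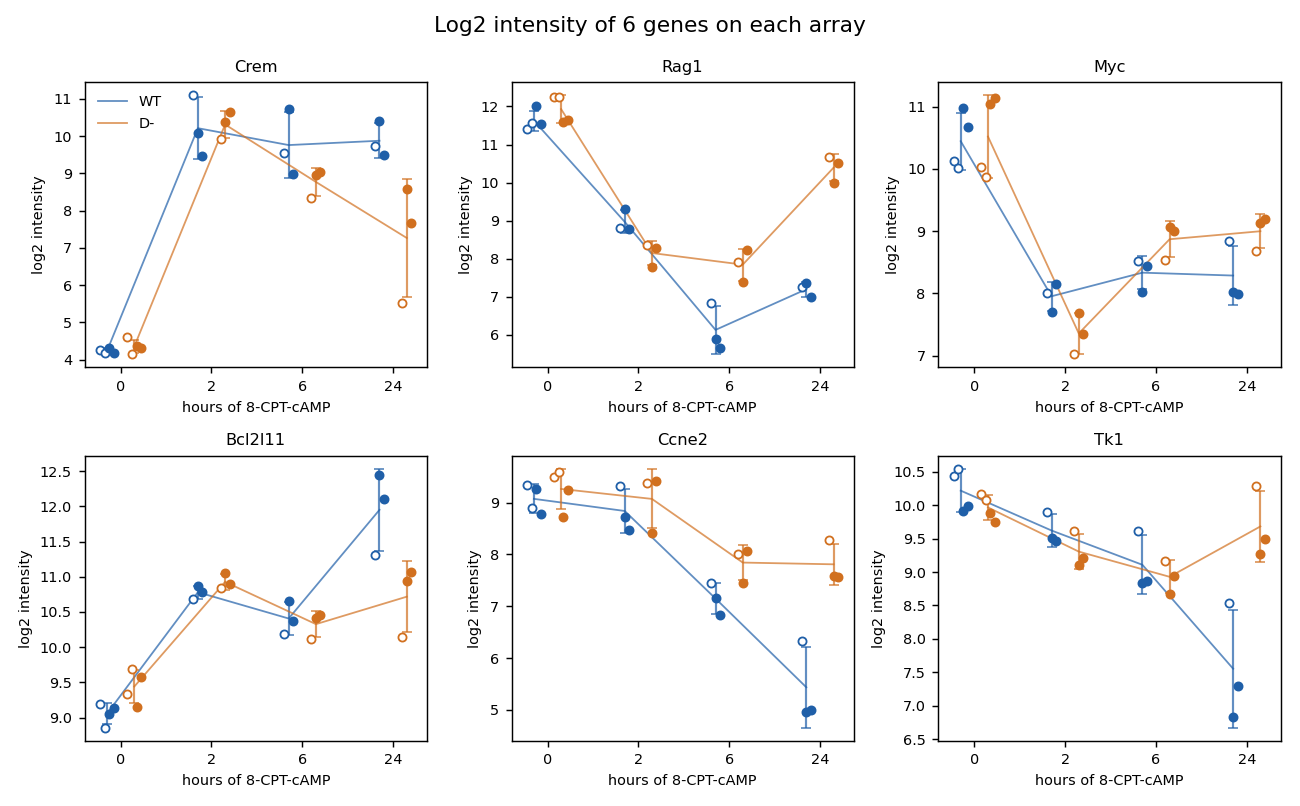
Log2 intensity on each array (vertical axis) against hours of 8-CPT-cAMP (horizontal axis) for Crem, Rag1, Myc, Bcl2l11, Ccne2 and Tk1, with WT in blue and D- in orange, open circles for cluster 1 and filled circles for cluster 2 arrays, and bars for the mean ± SD. Rag1 went from 11.6 ± 0.27 (n = 4) to 7.20 ± 0.19 (n = 3) at 24 h in WT and from 11.9 ± 0.36 (n = 4) to 10.4 ± 0.36 (n = 3) in D-.

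The interferon, glycolysis and myeloid lists gave no camera call in any of the 10 comparisons, though glycolysis had an unadjusted p = 0.0395 at 2 h in D- and 0.0166 between the untreated lines. Of 12 interferon response genes 6 were higher and 1 lower at 24 h in WT and 4 and 1 in D- (camera adjusted p = 0.313 and 0.307). Of 15 glycolysis genes 3 were higher and 3 lower at 24 h in WT and 3 and 2 in D- (camera adjusted p = 0.638 and 0.95). Of the markers of other cells, the stromal, B cell and erythroid lists had under 5 measured genes and were not tested with camera. Of 5 myeloid markers 1, Itgam, rose at 24 h in WT, by at least 1.24 (list camera adjusted p = 0.637). Of 3 stromal markers 2 rose at 24 h in WT, Acta2 by 1.47 ± 0.31 and Pdgfrb with both means under 5, the latter not without WT 24 h replicate 1 (adjusted p = 0.0939) or within cluster 2 (0.085). Of 4 B cell markers 2 rose at 24 h in WT and 1 rose and 1 fell in D-, and the only measured erythroid marker had a log2 change of -0.11 in WT and -0.096 in D- at 24 h and did not pass.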

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

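The tests chosen only after a result was seen are those of the 2 array clusters, of the S phase difference within a cluster, of a uniformly smaller D- response, of the shared direction of the untreated differences, of redrawn residuals, and of the order of the S phase and mitosis changes.

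The mean log2 intensity of the S phase list in untreated WT replicate 4 was 11.2, farther from the other 3 untreated WT arrays than Dixon's test for 4 values allows. Among 94 groups of 4 values tested, chance would give 4.7 such cases.

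Differences of response between D- and WT passed the test for 27 probe sets at 2 h, 66 at 6 h and 1500 at 24 h. Among those at 2 h Grb7 showed a D- minus WT log2 difference of 4.64, Tnfsf4 3.05, Palld 2.58 and Ctla2a -2.48. C4bp showed -2.76, Sgip1 -2.26 and Slamf1 -1.83. Among those at 6 h Chst1 showed 4.44, Ifitm2 3.03, Grb7 3.03, Ctla2b -4.22, Ctla4 -3.49, Ctla2a -3.07 and C4bp -3.03. Sgip1 showed -2.4, Pdgfrb -2.15, Prkcq -2.09 and Stat5b -0.695. The same comparison of lists gave medians at 2 h of -0.19 for mitosis, 0.13 for ribosome biogenesis and 0.16 for unfolded protein and amino acid stress genes, and at 6 h of -0.14 for mitosis, 0.22 for ribosome biogenesis and 0.24 for heat shock genes.

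At 24 h, of the cell cycle genes that differed, Tk1 showed 2.38, Cdc6 2.34, Cdc45 2.23, Ung 2.15, Chek1 2.39 and Aurkb 2.16. Ttk showed 1.96, Prc1 1.72, Cenpe 1.63, Ccne2 2.18, Cdk2 1.2, Ccnd3 1.07 and E2f1 1.04. Of T cell genes Rag1 showed 2.89, Bcl11b 1.36 and Lcp2 -1.22, and the apoptosis genes Bcl2l11 -1.62 and Birc3 -1.45. Crem showed -2.73, Junb -1.77, Nr4a1 1.49, Pde1b -1.51, Fkbp5 1.67, and the p53 targets Trp53inp1 -1.4, Sesn1 -1.17 and Zmat3 -1.16. Ccr7 showed -2.92, Ctla2a -4.89, Ctla2b -6.47, Pparg -3.95, Naip5 -3.62 and Cxcr6 -3.2. Nolc1 showed 1, Pa2g4 0.92, Psat1 1.11, Slc16a1 0.85, Hsph1 0.845 and Dnajb1 0.61. List medians at 24 h were 1.62 for S phase, 1.37 for mitosis, -0.302 for p53 targets and 0.32 for ribosome biogenesis. Values of genes with a group mean under log2 5, such as Ctla2b, Ctla2a, Pparg, Naip5, Cxcr6, Ccr7 and Crem, are fitted values and no measure of fold.

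For the treated comparisons and for the untreated lines, 1 of 35 splits, the real one, gave as many calls. That is the smallest share 35 splits allow, and it was not adjusted over the comparisons. It argues against chance assignment of arrays without excluding it. The highest other split gave 1291 against 3136 at 2 h, 2547 against 4601 at 6 h and 4838 against 6698 at 24 h in WT, 1356 against 2765, 1708 against 3863 and 2052 against 4250 in D-, and 1 against 577 between the untreated lines. For the differences of response the planned test does not exclude chance: 7, 6 and 13 of 100 splits gave at least 27, 66 and 1500 calls at 2, 6 and 24 h, and the highest others gave 425, 594 and 2814. A split can mix the lines unequally between untreated and treated arrays, and a difference between the lines then enters the contrast. Splits that mixed the lines in opposite ways, 27, 26 and 28 of those drawn, held 3, 2 and 4 of the large counts. The others held 3, 3 and 8, up to 82, 162 and 2537 calls. That group includes splits with the untreated lines evenly mixed and the treated lines unevenly, so the counts cannot tell line mixing from other causes. With line and time effects removed and residuals redrawn, 1 of 100 arrangements, the real one, was as large at each time (highest others 7, 7 and 493). Of another 100, with the real one, it was 1, 1 and 2 (highest others 20, 10 and 1734).

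S phase and mitosis genes fell further in WT than in D- at 24 h. The array clusters are argued against as the cause by the S phase median difference of 1.91 within cluster 2. RNA quality, by Gapdh alone, is argued against by a median of 1.32 with its 3' minus 5' difference as a covariate (1.3 for mitosis). The actin difference (1.86 in WT at 24 h, 1.72 untreated) was not used. A D- response that is smaller by 1 factor for every gene is argued against by the ratio of D- to WT mean response, 0.14 for S phase (0.0691 to 0.213 with 1 array left out) and 0.144 for mitosis, against 0.738 for ribosome biogenesis genes and a principal axis slope of 0.66 over all probe sets called in either line. Chance is not excluded by the planned splits of the count at 24 h, and 3 arrays per group cannot give an exact p below 0.1 for the list means. A difference between the lines in how far the cell cycle stops may underlie the pattern, as a hypothesis found on these data and not tested.

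The arrays fell into 2 clusters that cut across every group. A chance axis of the residuals is argued against, because weights from the WT arrays alone placed 13 of 13 D- arrays on the side given by their replicate number. Whether RNA quality underlies the clusters could not be told. Within the 16 arrays of cluster 2 the Gapdh 3' minus 5' deviation and the first axis correlated at Pearson r = -0.167 (permutation p = 0.54, Spearman rho -0.246, p = 0.36, r = -0.221 without the 2 arrays farthest from the median). Within the 10 of cluster 1 r was -0.651 (permutation p = 0.038, 0.076 adjusted over the 2 clusters, rho -0.474, p = 0.17) and -0.239 without the 2 farthest arrays, so it rests on those arrays, and no biological explanation was tested.

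Untreated D- and WT cells differed at least 2-fold in 185 probe sets. Stray untreated arrays as the cause of the direction are argued against, since 93.5% (173) differed in the same direction at 2, 6 and 24 h, with other arrays. How much of the size comes from stray arrays stays open, since 51.4% (95) were 2-fold apart the same way at all those times. An effect of the clusters on the size also stays open, since 67.6% (125) were 2-fold apart within both clusters, although all 185 had the same direction in both. An inherited difference between the lines remains a possible explanation and was not tested apart from these.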

How the results depend on the processing

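Fits with the cluster as a block, within a cluster, and with both the block and an estimated correlation were chosen after seeing the data. No named gene with a call, and none of the 19 list results recomputed, changed sign under any alternative. The majority direction of calls turned in D- at 2 h with median centring, in D- at 6 h with median centring, quantile normalization and the cluster block, in D- at 24 h within cluster 2, in WT at 2 h with no filter and in WT at 6 h with the replicate block (2596 higher, 2517 lower). Within cluster 1 it turned for 7 of the 10 comparisons, and leaving out 1 array turned it in WT at 2 and 6 h, in D- at 24 h and for the difference at 2 h. eBayes with trend and robust settings, quantile normalization, median centring, the filter at log2 7 and no filter kept all 10 counts within 1.5 times, and no scaling moved the median over all probe sets by over 0.1. Array weights gave 1050 calls between the untreated lines and 110, 353 and 3084 differences of response at 2, 6 and 24 h, and fitting only the groups compared gave 16 at 2 h. The cluster as a block gave 943 and 71, 138 and 2565. Cluster 2 alone gave 889 and 96, 215 and 2277, with a correlation of responses of 0.833 at 2 h and 0.821 at 6 h. Cluster 1 alone, with fewer arrays, gave 695, 1360 and 3631 in WT, 766, 837 and 826 in D-, 67 between the untreated lines and 1, 0 and 5 differences (limma, 757, 776 and 2625 at an unadjusted p under 0.05), with correlations of 0.796, 0.805 and 0.66. Probe sets called over all arrays changed less with treatment in cluster 1 than 2 (median 0.686 against 0.905 in WT at 24 h). In D- at 2 h they did not (0.727 against 0.722). No cause was tested.

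With 1 array left out, counts ranged from 2332 to 3014, 3579 to 4632 and 5781 to 6714 in WT at 2, 6 and 24 h, from 2117 to 2545, 2923 to 3488 and 3084 to 4460 in D-, and from 380 to 530 between the untreated lines. Differences of response ranged from 7 to 49, 35 to 110 and 962 to 2352, and correlations of responses from 0.835 to 0.873, 0.85 to 0.874 and 0.753 to 0.801. A call for a named gene ended in 161 of the values with 1 array left out and began in 7, against 3384 on the same side. Named calls that ended numbered 122 within cluster 1, 21 when only the groups compared were fitted, 12 within cluster 2, 12 with no filter, 3 with quantile normalization, 2 with median centring, and 1 with array weights, of 403 named values, and 1 of 364 with the filter at log2 7. Those that began numbered 12 within cluster 2, 7 with array weights, 6 with the cluster block, 4 when only the groups compared were fitted and 1 with quantile normalization. Of all 52 camera calls over the 10 comparisons, 5 held with an estimated correlation and 47 did not.

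Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at r between -0.468 and 0.655 over 36 pairs, 30 of them above 0.1, and 13 of 26 arrays correlated best with their own number. The replicate block gave 3581, 5113 and 6997 calls in WT, 3014, 4221 and 4615 in D-, 555 between the untreated lines and 39, 80 and 1825 differences, each within 1.5 times of the unblocked count, with correlations of 0.863, 0.87 and 0.783. It ended 5 named calls: Ctla2a and Sgip1 (difference at 2 h), Pdgfrb and Stat5b (6 h) and Plac8 (untreated). It began 8, in WT Nr3c1 at 2 h, Per1 and Prkaca at 6 h and Mcl1 at 24 h. In D- they were Nr3c1 at 2 h, Mcl1 at 6 h and Ccnd3 at 2 and 24 h. The mitosis list at 6 h in WT moved to camera adjusted p = 0.0571. Signal over background limits genes near log2 5, for which bounds are given.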

Other observations

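Among genes outside the preset lists, several had large changes in the treated cells. Sgip1, an endocytosis gene, rose in WT by at least 6.67 on the log2 scale at 2 h and by at least 7.7 at 24 h, and by 6.42 ± 0.29 in D- at 24 h. Ctla2a and Ctla2b, which encode cysteine protease inhibitors, rose in WT at 24 h by 6.14 ± 0.36 and by at least 4.79. Ramp3, a partner of calcitonin-family receptors, rose by at least 3.66 at 6 h in WT and by at least 3.9 at 2 h in D-. Tnfrsf18, which encodes the receptor GITR, rose at 6 h by 4.64 ± 0.42 in WT and 5.13 ± 0.42 in D-. Lmna, the lamin A gene, rose in D- by at least 4.77 at 6 h and 4.81 at 24 h, and Amot, an angiomotin gene, in WT by at least 5.47 at 2 h. The cytokine gene Il10 fell, with a bound of -2.58 or lower at 2 h and at 6 h in WT and -3.78 or lower at 6 h in D-.

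The order of the cell cycle changes was tested only after the list results were seen. The mean of the mitosis list minus that of the S phase list had moved at 6 h by 0.719 in WT and 0.65 in D- (exact permutation p = 0.029 for each, two-sided, the smallest that 3 against 4 arrays allow). At 2 h the shift was 0.0492 and -0.0833 (exact permutation p = 0.71 and 0.29), and at 24 h 0.404 in WT (0.029) and 0.05 in D- (0.71). All 6 arrays at 6 h had a lower S phase mean than the untreated mean of their line together with a raised difference. Entry into S phase may stop before cells leave mitosis, as a hypothesis found and tested on the same 6 arrays, and cell cycle position itself was not measured.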
